A study of Homo sapiens with 2 samples.

How the data were processed

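The data were 2 single-colour microarrays of human miRNAs, 1 hybridised with RNA from LoVo cells, an epithelial colorectal cancer cell line, and 1 with RNA from small extracellular vesicles (sEVs) shed by LoVo cells. Per the labels' protocols, cells were kept for 72 h in medium whose own vesicles had been removed by a spin at 160000 x g for 16 h. The sEVs were then taken from the medium by steps of centrifugation, filters of 100 kDa and 0.22 µm, a pelleting spin at 100000 x g for 70 min and a sucrose gradient spun for 2.5 h. RNA was extracted with the mirVana kit and labelled with Cy3, per the labels' protocols. The labels describe an amplified cRNA made from 0.2 µg of RNA, whereas the deposited arrays and their headers belong to a miRNA protocol with labelling spike-ins, and how the RNA was labelled is not settled by these sources.

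Both arrays were read with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. Per the file headers, the deposited processed intensity of each spot is its brightness after subtraction of a spatially fitted background, with no scaling between arrays, and it can fall below 0. The headers set the limit for a spot well above background with a multiplier of 13 on the background's spread. The same deposited files hold the mean spot intensity, the local background intensity, a total intensity per probe and a total intensity per miRNA, with detection at 3 errors and a value of 0.1 for a miRNA with no detected probe. The authors also deposited a value table on a log2 scale, and its column medians were -3.32 for both arrays because most miRNAs were at or next to the floor. Its scale was found from its values. The floor was log2 of 0.1, and the sorted columns were equal within 0.01 except at 9 ranks, as quantile normalization of the arrays gives. Across miRNAs the table correlated with the log2 sum of the detected probes' totals (r = 0.996 for cells and 0.999 for sEVs), and less with the deposited total per miRNA (r = 0.750 and 0.794). The tool that made the table is not given in the sources used here.

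Each array had 53144 spots, of which 50980 carried 5893 probes for 2549 human miRNAs. A probe had 5 to 20 spots, a miRNA had 1 to 4 probes, and probes were 9 to 23 bases long. Spots that Feature Extraction marked as population or non-uniformity outliers were left out (1502 on the cell array and 1390 on the sEV array), and control spots were used only where named. No spot was saturated. Processed intensities were scaled, set to a floor of 1, turned into log2 values, averaged over the spots of a probe, and expressed relative to the array's 75th percentile. That percentile was taken over the 413 human probes well above background on both arrays, and it was an intensity of 125.5 for cells and 111.9 for sEVs. A probe counted as well above background on an array when a share over 0.5 of its kept spots was. The difference of a miRNA, sEVs minus cells, was the mean over its probes well above background on both arrays. Errors are standard errors from the spread of replicate spots within each array, and they cover spot error only.

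With 1 array per group there was no test of the difference of any miRNA between sEVs and cells. The only p-values are of Fisher's exact tests of list shares, among the results flagged for a closer look. miRNAs were counted by a fixed size of 2-fold (1 on the log2 scale). A miRNA well above background on 1 array only was given a lower bound. This bound was the bright value minus the higher of the dim value itself and the lowest value of any probe well above background on the dim array. That lowest probe had an intensity of 11.1 on the cell array and 11.4 on the sEV array. Both arrays came from the same slide and the same scan, so no slide or scan differed between the groups, and the labels gave no other batch.

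Before the data were examined, 23 miRNA lists were fixed, together with the size rule, the alternatives and the rule for the miRNAs named. That rule took the 10 largest and 10 smallest differences, the 5 largest lower bounds in each direction, up to 3 members of each list with the highest mean value over both arrays, and 9 miRNAs named whatever their value. These 9 were miR-21-5p, miR-210-3p, miR-1246, miR-193a-3p, miR-100-5p, miR-10b-5p, miR-122-5p, miR-451a and miR-486-5p. The rule took 83 miRNAs, and any other miRNA named in the text was chosen after its values were seen or is a member of a list. The lists were the let-7 family, the miR-17-92 cluster with its paralogs, the miR-200, miR-15/16, miR-29, miR-30, miR-34 with miR-449, and miR-320 families, and the miR-23/27/24 clusters. Others held intestinal and other epithelial miRNAs, miRNAs raised in colorectal cancer, common reference miRNAs and miRNAs reported in serum exosomes of colorectal cancer patients. For other tissues there were lists of stromal markers, of blood cell and endothelial markers, of liver, muscle and neuron markers, of the chromosome 19 placental cluster, of pluripotency miRNAs, of the chromosome 14q32 imprinted cluster and of the miR-548 family. The last 3 lists held miRNAs numbered 1000 or above, and miRNAs with a GGAG or a UGCA motif in the part of the RNA that the longest probe covers. A list's median difference was placed among 10000 random lists of the same size, matched on mean value in 10 bins, as a description of these 2 arrays. Lists with under 3 measured members were given no such percentile. Some lists hold near-identical paralogs whose short probes can share target RNA, and their members are not independent.

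The alternatives tried were 5 other scalings, normexp background correction of the mean intensity with an offset of 50, the deposited total per miRNA, the brightest probe, the authors' value table, 2 other rules of detection, 2 other filters on dim miRNAs, outlier spots kept, a 4-fold size, the lower bounds added, and a smooth fit on GC content or on mean value removed. The sum of the detected probes' totals was added after the data were seen. Each value under an alternative was counted as the same, moved or reversed, and a value could be counted as the same after crossing the median. A list or a miRNA was counted as the same when it shifted by less than the SD of its spots over both arrays. It was counted as reversed only when its main value exceeded that SD and changed sign. No list median, relative to that of all miRNAs, exceeded it, so no list could be counted as reversed. Even so, 11 of 19 lists crossed the median of all miRNAs under at least 1 alternative. The counts also take in the 4 scalings that shift every miRNA alike, which cannot move a value relative to the median. Sides of the median are therefore given separately. The calculation was tested on arrays simulated from the cell array, with 30 miRNAs shifted by known folds. Of 10 miRNAs shifted 2.5-fold, 8 were measured and 8 passed the 2-fold size. Of 10 shifted 4-fold, 6 were measured and 6 passed, so the need for a probe well above background on both arrays lost 2 and 4 of them. The simulated sEV array was also dimmed as a whole, which can add to these losses. None of the 9 measured ones of 10 shifted 1.5-fold passed, and neither did any of the 190 unshifted ones that were measured. The median error of a log2 difference was 0.078 to 0.12, and 0.021 to 0.063 once the common shift of the unshifted miRNAs was removed. Both simulated arrays used the same probe means with spot noise added. These errors therefore leave out differences of probes between real arrays and can be too small.

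Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp. miRNA names are those of the array's design. For 67 of the 83 miRNAs of the naming rule, a gene of that name was found in the RefSeq gene table of assembly GRCh38.p14, and 51 of these lay inside another gene. No coordinates are given, because the probe positions in the deposited files mix genome builds.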

Results

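miRNAs were profiled on 1 array of LoVo cells and 1 array of the sEVs that these cells release, vesicles that carry RNA and protein between cells. The comparison asks how far the miRNAs of the vesicles differ from those of the cells that made them. Of 2549 human miRNAs on the array, 254 were well above background in cells and 244 in sEVs, and 2288 were so on neither array. The signals came from 8.69% of the miRNA spots on the cell array and 8.49% on the sEV array. There was no replicate array, so no difference below has a replicate check, and the number of arrays limits the precision.

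On these 2 arrays, the miRNA signals of LoVo sEVs differed little from those of LoVo cells. Of the 234 miRNAs measured by the same probe on both arrays, 0 were at least 2-fold higher and 0 at least 2-fold lower in sEVs, and the values correlated across miRNAs with a Pearson r of 0.998 and a Spearman rho of 0.995 (miRNAs are not independent replicates). Relative to the median log2 difference of these miRNAs, sEVs minus cells, miR-21-5p, an oncogenic miRNA encoded within VMP1, differed by 0.01 ± 0.02 (spot SE). let-7a-5p, of the tumour-suppressive let-7 family, differed by 0.03 ± 0.02, and miR-200b-3p, which represses the ZEB regulators of epithelial-mesenchymal transition, by 0.05 ± 0.02. With normexp background correction, miR-21-5p stood at -0.08, let-7a-5p at -0.06 and miR-200b-3p at -0.01. Set apart from this were a few dim miRNAs, led by miR-1287-5p and miR-1207-5p, which were well above background in sEVs and not in cells.

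**Figure D1:**
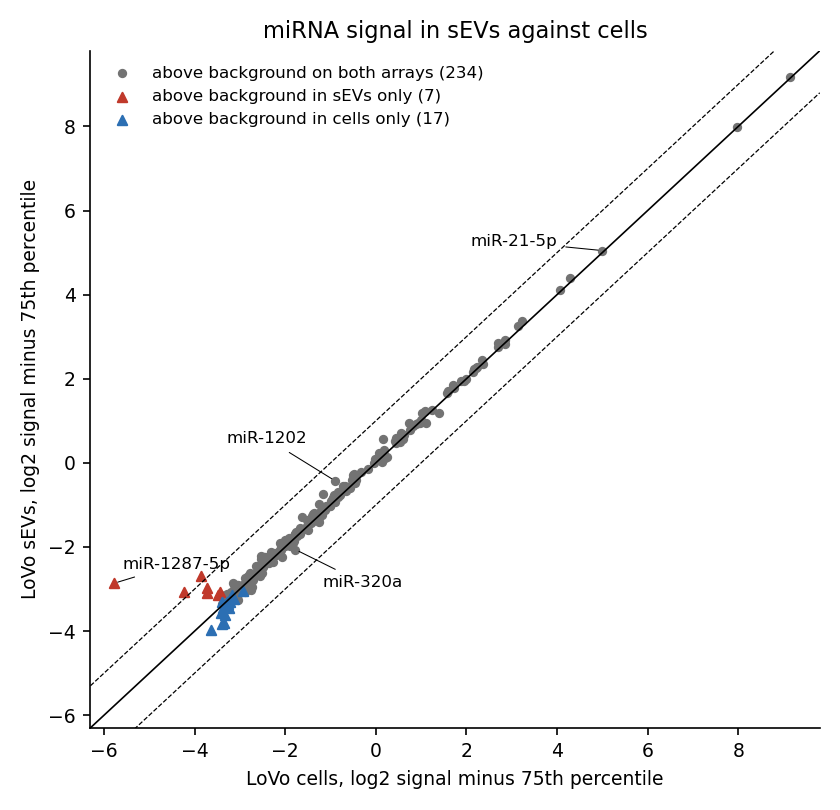
Log2 signal relative to the 75th percentile in LoVo sEVs (vertical axis) against LoVo cells (horizontal axis), with 1 point per miRNA, a solid line at equality and dashed lines at 2-fold. The 234 miRNAs above background on both arrays lie between the dashed lines, and the triangles are the 7 miRNAs well above background in sEVs only and the 17 in cells only, at their measured values.

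The median difference over the 234 miRNAs was 0.05, and 90.6% of them (212) differed by less than 0.2 on the log2 scale. Both depended on the scaling: the median was -0.22 with the 75th percentile of all human probes, -0.12 with no scaling and -0.01 with quantile normalization, and the share was 36.8%, 82.5% and 93.2%. Relative to the median, 92.7% lay within 0.2. Differences of measured miRNAs are therefore given relative to the median of the 234 miRNAs, in log2 units with the spot SE. Above it, miR-1202 stood at 0.42 ± 0.04, miR-4443 at 0.37 ± 0.05 and miR-6749-5p, encoded within ATG2A, at 0.35 ± 0.03. miR-1246, which shares its sequence with a fragment of the U2 small nuclear RNA, stood at 0.30 ± 0.04. The rest of the 10 highest were miR-6879-5p (0.28 ± 0.09), miR-101-3p, a repressor of the histone methyltransferase EZH2 (0.25 ± 0.19), miR-1587 (0.23 ± 0.15), miR-6875-5p (0.23 ± 0.04), miR-3944-5p (0.20 ± 0.07) and miR-1268a (0.20 ± 0.09). miR-101-3p and miR-1587 lay within 2 spot SEs of the median, and miR-1587 stood at -0.03 with the deposited total per miRNA. The deposited total can include the total of another miRNA, as described among the results flagged for a closer look. The 2 probes of miR-6875-5p disagreed (log2 differences 0.38 ± 0.05 and 0.17 ± 0.06), as did those of miR-6879-5p (0.50 ± 0.10 and 0.16 ± 0.16), and normexp correction gave 0.09 for either miRNA.

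Below the median, miR-320a had the lowest relative difference (-0.33 ± 0.07), measured by 1 of its 2 probes, and it turned to 0.06 when the probes were chosen by Feature Extraction's own detection. miR-4516 (-0.21 ± 0.02) and miR-20b-5p (-0.19 ± 0.04), of the miR-106a-363 cluster, were lower with small spot errors. miR-7641 stood at -0.27 ± 0.03, but its probes disagreed: the log2 differences were -0.32 ± 0.07 and -0.26 ± 0.04 on the dimmer probes and -0.07 ± 0.05 on the brightest, which gave -0.13 relative to the median. miR-362-5p (-0.31 ± 0.15), miR-1275 (-0.28 ± 0.16), miR-33b-3p, encoded within the lipid regulator SREBF1 (-0.26 ± 0.20), miR-4507 (-0.24 ± 0.22) and miR-181d-5p (-0.20 ± 0.14) lay within about 2 spot SEs of the median. The measured probes of miR-33b-3p disagreed (log2 differences -0.55 and 0.12). Its log2 difference was -1.19 with the deposited total and -1.16 with the sum of the detected probes' totals. With the deposited total, miR-1275 stood at 0.06 and miR-181d-5p at 4.19. That total can include the total of another miRNA, so these values are not separate measurements. miR-1915-3p stood at -0.22 ± 0.06. Among the largest differences, normexp correction with an offset of 50, which pulls dim values together, gave 0.20 for miR-1202, 0.16 for miR-4443, 0.20 for miR-6749-5p and 0.11 for miR-1246. With outlier spots kept, miR-1587 alone reached 2-fold, at 1.36 relative to the median.

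There were 7 miRNAs well above background in sEVs and not in cells. Their bounds below hold for the main scaling only. On the log2 scale they shift by -0.16 with no scaling and by -0.27 with the 75th percentile of all human probes. miR-1207-5p, encoded within the PVT1 locus, was at least 1.92-fold higher in sEVs, and it passed 2-fold (log2 difference 1.17 ± 0.07) where Feature Extraction's own detection was used. Its probe CCCCTCCCAGCC had a mean signal of 8.72 in cells and 16.7 in sEVs, and its probe CCCCTCCCAGCCT 8.78 and 18.4. miR-1287-5p, encoded within PYROXD2, was at least 1.70-fold higher, a bound set by the dimmest probe well above background on the cell array. Its own mean signals were 3.20 in cells and 15.6 in sEVs on the probe GACTCGAACCACTGA, and 1.74 and 15.3 on GACTCGAACCACTGAT. miR-5787, encoded within GNAI2, was at least 1.47-fold higher, and its 2 probes had measured differences of 1.15 ± 0.17 and 1.35 ± 0.41 on the log2 scale. For the remaining miRNAs the probes disagreed or the differences were small. miR-6780b-5p had a bound of 1.57-fold on 1 probe (0.75 ± 0.18) while its other probe, below the limit on both arrays, stood at -0.13 ± 0.21. miR-6124 had a bound of 1.46-fold on 1 of 3 probes (0.63 ± 0.33), with the others at -0.12 ± 0.15 and 0.26 ± 0.35. miR-200a-5p and miR-20a-3p had measured differences of 0.38 ± 0.21 and 0.34 ± 0.12. miR-7845-5p, chosen after its values were seen, was well above background on neither array, but on both of its probes every kept sEV spot was brighter than every kept cell spot.

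**Figure D2:**
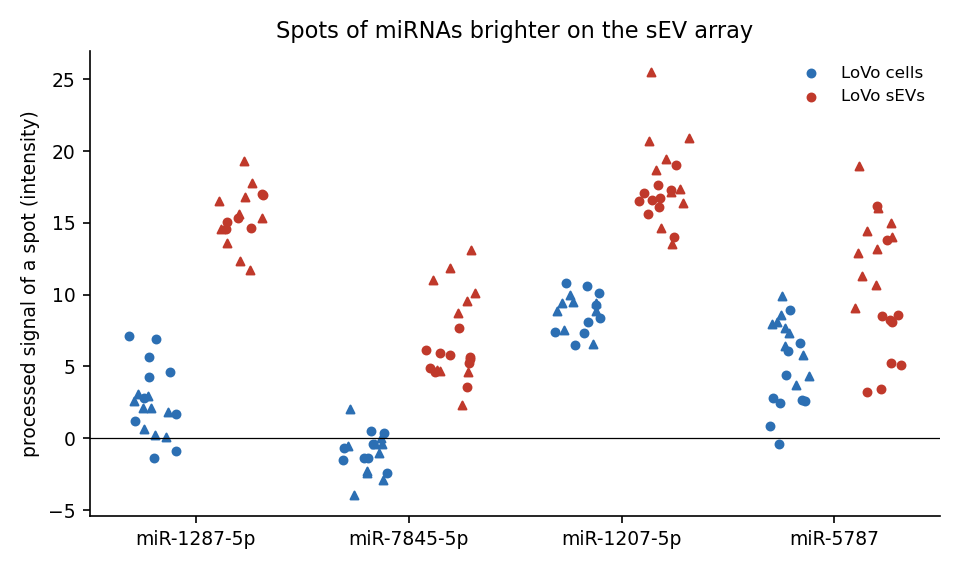
Processed signal of each kept spot (vertical axis, intensity) of miR-1287-5p, miR-7845-5p, miR-1207-5p and miR-5787 on the cell array (blue) and the sEV array (red), with circles and triangles for the 2 probes of each miRNA. For miR-1287-5p the spots of both probes average 3.20 and 1.74 in cells and 15.6 and 15.3 in sEVs, with no overlap.

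The 17 miRNAs well above background in cells and not in sEVs lay close to the limit of detection. Under the main scaling, the 5 with the largest bounds had measured log2 differences, sEVs minus cells, within about 2 spot SEs of 0. With no scaling, differences shift by -0.16, so their distance from 0 depends on the scaling. The 5 were miR-4664-3p (-0.22 ± 0.10), miR-218-5p (-0.13 ± 0.13), miR-449a (-0.11 ± 0.21), miR-4763-3p (-0.16 ± 0.16) and miR-30a-3p (-0.09 ± 0.13). No miRNA seen on 1 array only had a bound of 2-fold or more in either direction.

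List medians lay close to that of all miRNAs, and 11 of the 19 lists with a measured member were on its other side under at least 1 of the 13 alternatives that can move a list against it. Those 11 were the let-7, miR-200, miR-15/16, miR-29 and miR-320 families, the miR-23/27/24 clusters, and the lists of intestinal and other epithelial miRNAs, of miRNAs raised in colorectal cancer, of serum exosomes, of stromal markers and of miRNAs numbered 1000 or above. Of the other 8, the lists of 14q32 and of the UGCA motif lay on the median under 1 alternative each, and 6 kept their side. The let-7 family was measured in full, with 9 of 9 members on both arrays, and its median stood 0.02 above that of all miRNAs, at the 77.4th percentile of random lists of like signal. The oncogenic miR-17-92 cluster and its paralogs stood lowest of the lists: 11 of its 12 members on the array were measured, 10 of them below the median of all miRNAs, and its median was -0.06 relative to it, at the 0.18th percentile. Its members included miR-20a-5p (-0.08 ± 0.03), miR-106b-5p (-0.04 ± 0.03), miR-92a-3p (-0.16 ± 0.03) and miR-93-5p (-0.13 ± 0.03). Closer to the median were miR-19b-3p (-0.01 ± 0.02) and miR-25-3p (-0.01 ± 0.02), and miR-18b-5p lay above it (0.03 ± 0.10). The list's median stayed below that of all miRNAs under each of the 13 alternatives that can move it. Near-identical members such as miR-20a-5p and miR-20b-5p can share target RNA on short probes, so they are not independent.

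Of the epithelial lists, 3 of 5 members of the miR-200 family were measured, with a median 0.01 above that of all miRNAs (57.8th percentile), which was below it with quantile normalization, the only other scaling that does not shift every miRNA alike. The measured members were the clustered miR-200b-3p, miR-200a-3p and miR-429, while miR-200c-3p and miR-141-3p, which are encoded together at another locus, were well above background on neither array. Among intestinal and other epithelial miRNAs, 2 of 6 were measured. These were miR-192-5p, a marker of gut epithelium, at 0.01 ± 0.05, and miR-203a-3p at 0.03 ± 0.08. The value of miR-203a-3p came from 1 of its 2 probes. Its other probe, well above background in cells only, had a log2 difference of -0.33 ± 0.12. miR-203a-3p lay below the median under 6 of 10 alternatives, at -0.19 with no filter on dim miRNAs. The gut epithelial miR-194-5p and miR-215-5p and the neuroendocrine miR-375 were well above background on neither array. The miRNAs raised in colorectal cancer had 6 of 9 members measured and a median of 0.04 (68.1th percentile), with miR-96-5p at 0.10 ± 0.02 and miR-221-3p at 0.07 ± 0.02. Of the miRNAs reported in serum exosomes of colorectal cancer patients, 4 of 7 were measured (miR-1246, miR-23a-3p, let-7a-5p and miR-21-5p), with a median of 0.03 (76.4th percentile) that was -0.04 with normexp.

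The remaining families lay near the median of all miRNAs. The miR-15/16 family, repressors of BCL2, had a median of 0.05 over 5 of 7 members (80.6th percentile), the miR-30 family -0.02 over 5 of 5 (27.8th), and the miR-320 family 0.03 over 5 of 5 (67.8th). The miR-29 family, which represses collagen genes, stood at -0.01 over 3 of 3 (41.4th percentile) and the miR-23/27/24 clusters at -0.03 over 5 of 5 (18.6th), and each lay on the other side of the median with quantile normalization. In the p53-linked miR-34 and miR-449 family, miR-34a-5p stood at 0.02 ± 0.05 and miR-34c-5p at 0.01 ± 0.06, and miR-449a was well above background in cells only. Common reference miRNAs had a median of -0.03 over 6 of 8 members (9.78th percentile), among them miR-16-5p (-0.06 ± 0.02), miR-103a-3p (-0.08 ± 0.03) and miR-107 (0.07 ± 0.02).

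Of the miRNAs named whatever their value, hypoxia-induced miR-210-3p stood at -0.13 ± 0.06, miR-193a-3p at -0.07 ± 0.07 (0.74 with the deposited total, which can include another miRNA's total), miR-10b-5p at -0.04 ± 0.11 and miR-100-5p within 0.01 of the median (SE 0.05). Liver-specific miR-122-5p and the red blood cell miRNAs miR-451a and miR-486-5p were well above background on neither array.

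Markers of other tissues were mostly below background on both arrays. The measured share was 37.5% of stromal and 30% of blood cell and endothelial markers. It was 60% of the miR-200 family, 33.3% of intestinal and other epithelial miRNAs and, among all miRNAs on the array, 234 of 2549. None of the 10 liver, muscle and neuron markers, the 48 members of the placental cluster on chromosome 19, the 20 pluripotency miRNAs or the 70 members of the miR-548 family was measured, and of the 93 members of the imprinted cluster at 14q32 only miR-494-3p was (0.09 ± 0.03). Blood cell and endothelial markers had 3 of 10 members measured, with a median of -0.03 (11.4th percentile). These were endothelial miR-126-3p (-0.14 ± 0.06) and the blood cell miRNAs miR-155-5p (-0.02 ± 0.08) and miR-142-3p (-0.03 ± 0.06). Stromal markers had 3 of 8 measured and a median of 0.12 (95.7th percentile), which was -0.04 with no filter on dim miRNAs, with miR-199a-5p at 0.16 ± 0.10 (-0.13 with no filter), miR-199a-3p at 0.12 ± 0.04 and miR-214-3p at -0.11 ± 0.05. The smooth muscle miRNAs miR-143-3p and miR-145-5p were well above background on neither array.

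The lists cut by number and by GGAG reached the upper end of the random lists. miRNAs numbered 1000 or above, which were annotated late, were measured for 92 of 1639 members, with a median only 0.01 above that of all miRNAs but at the 98.9th percentile. They made up 92 of the 234 measured miRNAs, 9 of the 10 highest differences and 5 of the 10 lowest. Another 5 were well above background in sEVs only and 11 in cells only. miRNAs with GGAG, a motif tied to vesicle loading by hnRNPA2B1, had 34 of 302 members measured and a median of 0.04 (98.2th percentile), which was 0.003 with no filter on dim miRNAs. Members with GGAG made up 34 of the 234 measured miRNAs, 6 of the 10 highest differences and 1 of the 10 lowest. Those with the highest mean value were miR-6085 (0.16 ± 0.03), miR-5739 (0.11 ± 0.03) and let-7e-5p (0.01 ± 0.03, below the median with quantile normalization). The lists overlap, since 22 of these 34 are also numbered 1000 or above. miRNAs with UGCA had 22 of 252 members measured, 9 of them from the miR-17-92 list, and a median of -0.02 (11.7th percentile). Of the 16 lists with a percentile, 2 lay above the central 95% of random lists and 1 below it.

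**Figure D3:**
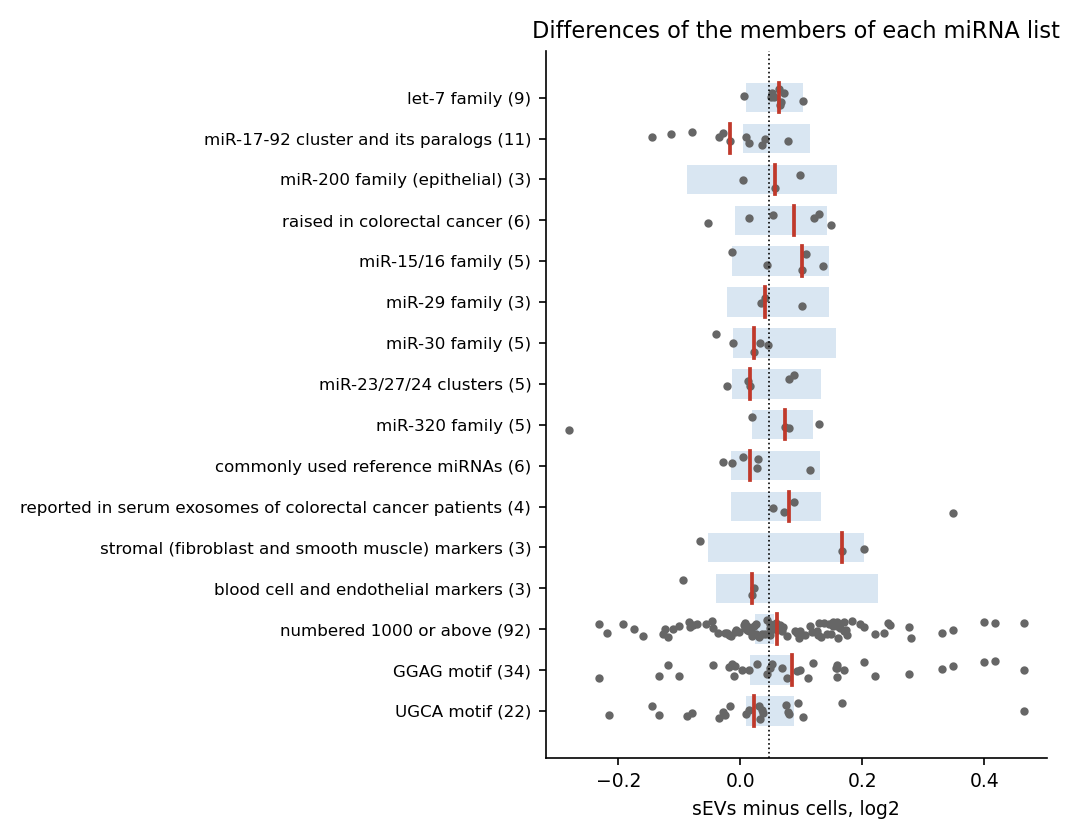
Log2 difference of sEVs minus cells (horizontal axis) of each measured member (grey points) of the 16 lists with at least 3 measured members, with the list's median (red), the central 95% of medians of random lists (blue band) and the median of all 234 miRNAs (dotted line). The number of measured members is in brackets, and the medians run from -0.02 for the miR-17-92 list to 0.17 for stromal markers, whose median lay below that of all miRNAs under 2 of 13 alternatives.

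Spot error was small beside the range of signals but close to the size of most differences. The SD over the spots of a probe had a median of 0.12 on the cell array and 0.14 on the sEV array. With the spots of each probe split at random, the SD of differences over the 234 miRNAs was 0.09 between the parts of the cell array, 0.12 between those of the sEV array, and 0.13 between the arrays for either part. The differences of the 2 parts correlated across miRNAs (r = 0.42). The 31 control probes were 4 of labelling spike-ins, 4 of hybridisation spike-ins and 23 others. For these 23, the sources used here do not say whether they bind RNA of the sample. The 31 differed between the arrays by -0.04 to 0.33 (unadjusted for the median), the upper end on a dim probe of the 23 (0.33 ± 0.10). Beyond that range by over 2 spot SEs lay 2 miRNAs above it and 7 below it. The range was not centred on the miRNAs, so these counts carry no direction. Mean differences were 0.21 for hybridisation spike-ins, 0.15 for the other 23 control probes and 0.01 for labelling spike-ins, against a median of 0.05 for the miRNAs.

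**Figure D4:**
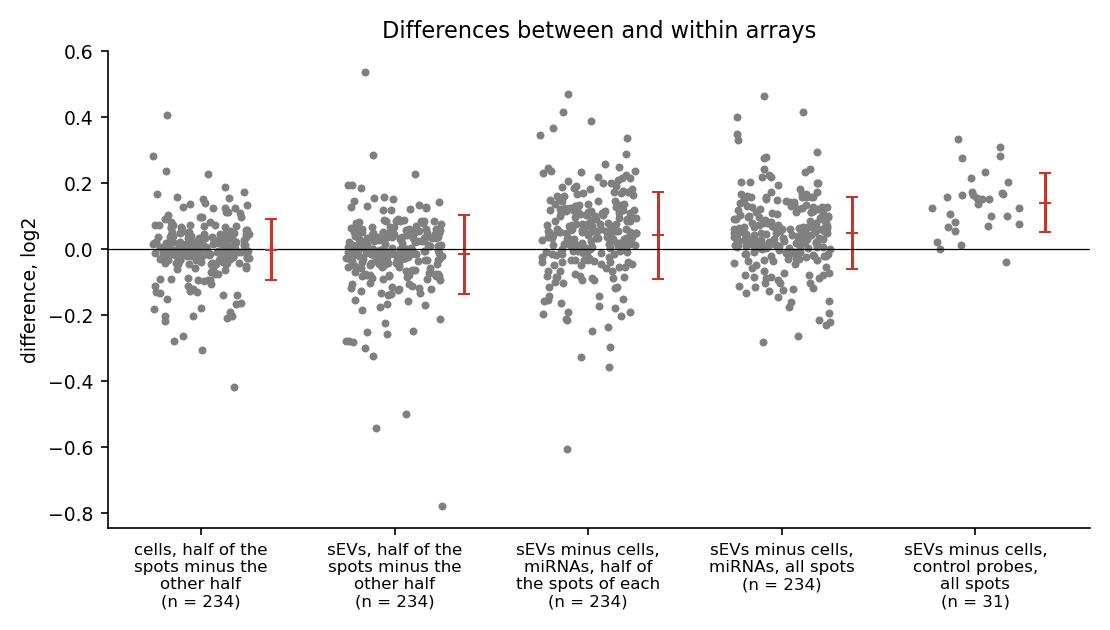
Log2 differences (vertical axis) within each array, between the arrays on part of the spots or on all of them, and of control probes, with 1 point per miRNA or control probe and the mean with SD (red) beside each. The SD is 0.09 and 0.12 within the arrays, 0.13 between them on part of the spots, 0.11 on all spots and 0.09 for the control probes.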

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

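All tests in this part were chosen after the patterns they address were seen in these data. For the test of the spots around miR-1287-5p and the test of totals over all probes, the prediction was written before that test was run. For the other tests it was written after their results. Feature Extraction's total signal per miRNA, the deposited total, was used above only as an alternative. It was at least 2-fold above the sum of that miRNA's detected probes for 77 miRNAs on the cell array and 71 on the sEV array. A candidate explanation is a summing error that adds the total of the miRNA before it in name order, and no biological explanation was tested. Of the 164 totals over 1% above their own sum, 164 equalled that sum plus the total of the detected miRNA before it, within 1%. Raised totals were found for 83 of the 83 detected miRNAs on the cell array whose first probe by name was not detected. On the sEV array they were found for 81 of 81. Where the first probe was detected, 264 of 264 totals in cells and 256 of 256 in sEVs equalled their own sum, within 1%. The total of 364.4 for miR-16-2-3p on the cell array was its own 0.565 plus the 363.9 of miR-15b-5p. Undetected probes being counted in is ruled out, since 0 of the 164 equalled the sum over all probes.

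The likeness of the sEV and cell arrays was weighed against signal that does not come from the RNA. Of the epithelial lists 5 of 11 members were well above background on both arrays, against 6 of 28 markers of other tissues (3 of 8 stromal, 3 of 10 blood and endothelial, 0 of 10 liver, muscle and neuron; Fisher's exact test, two-sided, p = 0.23), 0 of 148 members of the placental, pluripotency, miR-548 and liver, muscle and neuron lists (p = 5.8e-07) and 7 of 259 members of all other-tissue lists (p = 2.8e-05). The last 2 values decide nothing, since the 4 lists with no measured member were joined after their counts were seen. Their members are also part of the 259, and paralogs among them are not independent. Signal that does not come from the RNA therefore stays open. This includes signal driven by probe sequence, since the lists were not matched by sequence. The same RNA on both arrays stays open too: at least 2-fold apart with every kept spot separated in scaled signal were 3 miRNAs over all of their probes (miR-1207-5p, miR-1287-5p and miR-7845-5p) and 8 on at least 1 probe (2 miRNAs over all probes with the scaling to the 75th percentile of all probes), but none of these probes had a mean signal above 18.4, too near the floor to decide it. sEVs that hold the cells' miRNAs in like proportions, or cell RNA in the sEV preparation, cannot be told apart from it or from each other, since no sample separates them and the spread of bright miRNA probes beyond spot error, 1.13 times that of control probes and 1.44 times that within their kinds, decides nothing.

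miR-1287-5p was brighter on the sEV array. Spot error among the kept spots is ruled out as the cause, since 16 of its 16 kept sEV spots lay above the highest of 19 kept cell spots. It had 20 spots on each array, and those not kept were left out as outliers and not compared. A mark on an array is ruled out too: spots of undetected miRNAs within 5 rows and columns differed by a median of 0.058 in signal over 1517 spots, against 13.0 for its own. A selective presence in sEVs, an RNA from the medium or from another source that binds the same probes, and a difference of hybridisation between the arrays remain open, and none of them was tested.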

How the results depend on the processing

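The sum of the detected probes' totals was chosen after the data were seen, and the other alternatives before. Of the values that answer the comparison, 389 were the same and 23 moved under an alternative. Of the others, 1012 were the same (some across the median), 24 moved and 3 reversed. For the lists these labels say little, since the SD of spots they were held to was wider than any list's distance from the median. The cause of a change was not tested unless named. The count of miRNAs at least 2-fold higher was 3 with the deposited total per miRNA (miR-181c-5p, miR-181d-5p and miR-4485-5p), 1 with Feature Extraction's detection (miR-1207-5p), 6 with no filter on dim miRNAs, and 1 with outlier spots kept (miR-1587). Those 6 were miR-1207-5p, miR-1287-5p, miR-4487, miR-4646-5p, miR-5787 and miR-7845-5p. The count at least 2-fold lower was 1 with the deposited total and 1 with the sum of the detected probes' totals, both miR-33b-3p. For miR-181c-5p the error in the total gives the cause, as its sEV total of 98.4 was its own 2.08 plus 96.3 of miR-181c-3p. The same error can enter another value given with the deposited total where the first probe of the miRNA was not detected on an array. It was not traced for each. miRNAs in sEVs only numbered 13 with Feature Extraction's detection, 2 with every kept spot required and 0 in the brighter part of the miRNAs, where those in cells only also numbered 0. Those counts of 0 say little, since that part was chosen by mean value over both arrays, which is low for a miRNA dim on 1 array. One-sided counts were not computed for the deposited total, the sum, the authors' value table or no filter.

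The correlation of sEV and cell values across miRNAs, as Pearson r, was 0.9993 with normexp, 0.979 with the deposited total, 0.9980 with the authors' value table and with the sum of the detected probes' totals, 0.997 with Feature Extraction's detection and with outlier spots kept, and 0.990 with no filter. The correlation of sEV and cell values across miRNAs, Spearman rho, was 0.967 with the deposited total, 0.983 with Feature Extraction's detection, 0.996 with every kept spot required, 0.776 with no filter and 0.990 with outlier spots kept. Of 19 lists, 11 lay on the other side of the median of all miRNAs under at least 1 of the 13 alternatives that can move them, and 34 of 70 named miRNAs under at least 1 of 11. The furthest values with normexp were -0.043 for the list reported in serum exosomes of colorectal cancer patients, -0.046 for let-7, -0.024 for miR-15/16 and -0.022 for miRNAs raised in colorectal cancer. They were -0.044 for stromal markers with no filter, -0.17 for intestinal and other epithelial miRNAs with Feature Extraction's detection, -0.032 for miR-200 and -0.0035 for miRNAs numbered 1000 or above with the authors' value table, 0.019 for miR-29 and 0.0031 for miR-23/27/24 with quantile normalization, and -0.0011 for miR-320 with outlier spots kept. Relative to the median, miR-320a turned to 0.059 with Feature Extraction's detection and 0.036 with no filter, where both of its probes enter, and miR-5100 to -0.022 with normexp. With the deposited total, miR-1275 turned to 0.063, miR-1587 to -0.034, miR-181d-5p to 4.19 and miR-193a-3p to 0.74, and with normexp miR-15b-5p to -0.024, miR-29b-3p to -0.024 and miR-200b-3p to -0.012. miR-199a-5p turned to -0.13 with no filter, miR-30c-5p to 0.064 with Feature Extraction's detection and miR-27a-3p to 0.0065 with quantile normalization. Of the 234 miRNAs, 74.4% were higher in sEVs, against 3.42% with the 75th percentile of all probes, 32.9% with the median, 10.68% with no scaling, 44.4% with quantile normalization and 14.5% with control probes, so the split carries no direction. Signal over background limits the comparison to the 8.69% and 8.49% of spots well above it.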

Other observations

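The values of this part were looked for after the data were seen. Among all human probes, 11 probes of 8 miRNAs were at least 2-fold apart with every kept spot of 1 array above every kept spot of the other in scaled signal, and all 11 were brighter on the sEV array. Besides miR-1287-5p, miR-1207-5p, miR-5787 and miR-7845-5p, they belonged to miR-198, miR-223-5p, of the myeloid miR-223 gene, miR-4487 and miR-4646-5p. miR-4487 had a mean signal of -1.32 in cells and 11.1 in sEVs on 1 probe, and miR-223-5p -0.36 and 2.99. Most of these signals were below the level counted as well above background, and 0 probes were separated in the other direction. These counts depended on the scaling. With no scaling 8 probes were brighter on the sEV array and 3 on the cell array, and with the 75th percentile of all probes 7 and 4. Both probes of miR-1287-5p and of miR-7845-5p stayed among those brighter on the sEV array under each scaling checked.

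The control probes differed by kind. Without scaling, spike-ins added before labelling were lower on the sEV array by a mean log2 difference of -0.15 over 4 probes, spike-ins added at hybridisation differed by 0.04 over 4 probes, and the other 23 control probes by -0.01. The median difference of the 234 miRNAs on the same scale was -0.12.

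For 157 miRNAs with 2 probes well above background on both arrays, the differences of the probes correlated across miRNAs with r = 0.35. For the 49 of them whose probes both had a spot SE under 0.05, r was 0.79.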
